A study of Mus musculus with 8 samples.

How the data were processed

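RNA-seq was performed on mouse molar tooth germs, the embryonic buds of the molar teeth, which were dissected from BRE-GFP embryos, cultured in vitro and treated for 1 day. BRE-GFP embryos carry a green fluorescent reporter of BMP-Smad signalling. Per the labels, E12.5 germs received DMSO (the solvent), SB431542 (an inhibitor of the TGF-beta and activin type I receptors) or SIS3 (an inhibitor of Smad3), and E13.5 germs received DMSO as a stage control. The doses are not given in the sources used here. Each of the 4 groups has 2 deposited columns of counts, and columns were matched to samples by their names.

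The deposited values are estimated counts per gene, given as whole numbers and not scaled between libraries. The submitters' processing notes name Salmon, HISAT2, SAMtools, deepTools and DESeq2 without roles or versions, and the build mm10. The annotation and the counting options are not given in the sources used here. Salmon divides reads that match several transcripts by estimation, so counts of near-identical genes can move between copies. Per the labels, total RNA was used and the libraries were made with 2 kits. Both SIS3 libraries were made with the TruSeq RNA kit v2, which selects polyadenylated RNA, and every other library was made with the SMARTer Universal Low Input kit, which primes at random. Kit and SIS3 therefore cannot be told apart, and each SIS3 value holds the effect of the inhibitor plus that of the kit.

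Before any test the 2 columns of each group were compared. In the E12.5 DMSO, SB431542 and E13.5 DMSO groups the column totals differed by 0.00168%, 0.00212% and 0.00749%. Over genes with 1 annotated transcript, the mean squared difference between the columns was 1.19, 1.05 and 1.12 times the binomial variance of dividing 1 set of reads at random. Most genes have more transcripts and exceeded this: the ratio was 3.535, 3.057 and 2.785 for genes with 2 to 6 transcripts (5881, 5794 and 5130 genes) and 4.77, 4.79 and 4.21 for genes with 7 or more. In the SIS3 group the totals differed by 44.5% and the ratio was 28.4 over genes with 1 transcript and 25.3 over those with 2 to 6. The paired columns of the 3 SMARTer groups thus differed by about the sampling noise for genes with 1 transcript, by more for the others and by less than the SIS3 pair in each class, and each pair was summed and counted as 1 library. This left 5 libraries: 1 each for E12.5 DMSO, E12.5 SB431542 and E13.5 DMSO, and 2 for SIS3. The plan written before the data were examined had treated all 8 columns as replicates. That fit is given as an alternative. Whether the 2 SIS3 libraries came from separate cultures is not given in the sources used here, so the spread between them may be technical.

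Differences were tested with edgeR 4.0.16 (R 4.3.3), on TMM-normalised counts of the genes kept by filterByExpr (19022 genes), with a quasi-likelihood F test, robust estimates, the group as the only factor and Benjamini-Hochberg adjustment at 0.05 within each comparison. The fit has 1 residual degree of freedom, from the pair of SIS3 libraries, plus 12.5 borrowed across genes. The 3 lone libraries are assumed to vary as the SIS3 libraries do, and a comparison of 2 lone libraries has no replicate check of its own. The common biological coefficient of variation was 29.3%, and the median 95% confidence interval of a log2 fold change reached 1.19 to either side for SB431542, 1.01 for SIS3 and 1.26 for the stage comparison. Library totals ran from 5995709 to 30975010 counts, and 3 counts, the floor used for a library or group at 0, correspond to 0.097 to 0.5 CPM (counts scaled to the total of the library). Counting intervals of ratios and floors, unlike the confidence intervals of the fit, cover counting error only, since the reads carry no molecular identifiers in the labels' protocols.

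The scripts were tested on simulated counts with 200 changed genes. For SB431542, 7.5% of 2-fold, 61.2% of 4-fold and 87.9% of 8-fold changes were recovered over 18010 genes, with 3 false calls. For SIS3 the shares were 7.5%, 64.2% and 97% with 10 false calls, and for the stage comparison 3%, 58.2% and 90.9% with 4 false calls. With no changed gene there were 0 calls in each comparison. A 2-fold change is thus mostly missed at this number of libraries, even in this setting. The changes were planted only in genes above 5 CPM. Each gene was given the spread typical of its expression level, and the lone libraries the same spread as the SIS3 pair. The simulation therefore cannot give the recovery or false calls where single genes or lone libraries vary more.

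Lists of genes (pathways, cell types and technical classes) were fixed with the plan, and 33 had at least 5 tested members, of which 2 (non-polyadenylated RNAs and replication-dependent histone genes) hold the same 59 tested genes. For the lists described, the count of called members is given over all genes, and for some of them also adjusted over the list alone, which can give more calls. Because groups are single libraries, whether a list stands apart is described by the percentile of its median log2 fold change among 10000 random lists of the same size, drawn from protein-coding genes matched on mean expression in 20 bins. Such a percentile describes these libraries and is not a p-value. Extreme percentiles were common: 19, 18 and 7 of the 33 lists lay below the 2.5 percentile for SB431542, SIS3 and the stage. Above the 97.5 percentile lay 3, 4 and 4 lists, where 1.7 outside both bounds are expected by chance. The planned test, limma's camera (limma 3.58.1, preset correlation 0.01, Benjamini-Hochberg over the lists), is given as the number of lists called, also with an estimated correlation. A list with an extreme percentile need not be called by it. The estimated correlation rests on the 1 residual degree of freedom. That setting could hardly call any list, so an absence of calls in it decides nothing. Where a group had 0 counts for a list member, the median was also computed with that member at its bound of 3 counts over the group.

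Genes were named by a rule written with the plan. It takes, per comparison, the 6 largest increases and the 6 largest decreases among called genes with a mean of at least 5 CPM over the 8 columns, no overlap between the groups and no predicted, clone or pseudogene symbol. For SIS3 it also leaves out the members of the mitochondrial, ribosomal protein and non-polyadenylated lists. The ribosomal protein list was set by a pattern of symbols that does not match the retrogene Rps27rt, which the rule therefore names. It adds up to 4 members with the smallest adjusted p of each list described, and 12 fixed genes, of which Shh was not tested because its counts were 6 or fewer in every library, and 1 is not reported here. As no gene was called for SB431542, its largest changes were chosen in the 8-column fit, and their values come from the 5-library fit.

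Identifiers were matched to the GENCODE M21 annotation of GRCm38, the same assembly as mm10. Of 35896 genes in the table, 35437 matched, of which 21718 are protein coding and 13196 are pseudogenes. Shared sequence was measured as the percent of a gene's 31-mers found in another gene of the table. Correlations of fold changes between comparisons were set beside 50 simulated sets of unchanged libraries that share the control. Alternatives were DESeq2 1.42.0, RLE normalisation, other filters on low counts, a minimum fold of 1.5, removal of trends on GC content and gene length, leaving out each deposited column, and fits without classes of genes. The fits without classes of genes were chosen after seeing the data. The exception is the planned fit of the SIS3 comparisons without non-polyadenylated, mitochondrial, ribosomal protein and predicted genes. The fits on 8 columns were planned, and summing the paired columns was chosen after the columns had been compared.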

Results

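Gene expression was measured by RNA-seq in cultured mouse molar tooth germs at E12.5 after 1 day with DMSO, SB431542 or SIS3, and at E13.5 after 1 day with DMSO. The series addresses BMP-Smad signalling in the dental mesenchyme, the neural-crest-derived tissue under the dental epithelium. After the paired columns of 3 groups, which differed by about the sampling noise for genes with 1 annotated transcript and by more for the others, had been counted as 1 sample each, the data held 1 E12.5 DMSO library (30975010 counts), 1 SB431542 library (28161788), 1 E13.5 DMSO library (17519118) and 2 SIS3 libraries (5995709 and 9427262). Values are estimated counts, and folds are from the edgeR fit of these 5 libraries. Every spread comes from the pair of SIS3 libraries.

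The first comparison asked what 1 day of TGF-beta and activin receptor inhibition changed at E12.5. In the SB431542 library Pmepa1 (ENSMUSG00000038400; GRCm38 chromosome 2, 173224458 to 173276533, minus strand), a direct Smad target that feeds back on TGF-beta signalling, stood at 13.4 CPM against 49.2 CPM in DMSO (log2 fold change -1.93, SE 0.41, n = 1 against 1), and Skil, which encodes the Smad corepressor SnoN, at 48.3 against 171 CPM (-1.88, SE 0.40). Matrix genes were also low in it: Mfap4, encoding a microfibril protein, had a log2 fold change of -2.35 (SE 0.37) and Fbln5, encoding an elastic fibre protein, of -2.86 (SE 0.53). The surface epithelium keratin gene Krt17 stood at 0.639 against 16.2 CPM (log2 fold change -4.70, SE 0.79). Krt4, another such gene, stood at 0.142 CPM, near the floor, against 2.45 CPM (-4.10, SE 0.85). It reached the mean of 5 CPM of the naming rule only through the E13.5 library (43.5 CPM). None of the genes named here passed the test: edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 0 of 19022 genes, with a smallest adjusted p of 0.272. At an unadjusted p under 0.05 there were 108 genes higher and 127 lower, and DESeq2 called 0 higher and 4 lower.

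As groups, the lists of TGF-beta output and matrix lay low in the SB431542 library. They are not separate evidence, since both hold Fn1, Col1a1, Col1a2, Col3a1, Col5a1, Postn and Lox. The 29 tested Smad2/3 target genes had a median log2 fold change of -0.38, below all 10000 random lists, with 0 members called over all genes and 3 lower when adjusted over the list alone. The 41 extracellular matrix genes had a median of -0.41, also below all random lists, with 6 lower when adjusted over the list alone. Lower still were the 30 dental epithelium genes, at a median of -1.32, and the 17 oral and skin surface epithelium markers, at -1.60. Adjusted over the list alone, 0 dental epithelium genes and 2 surface epithelium markers were lower. Mitotic and S-phase genes (-0.65), replication-dependent histone genes (-0.61), chondrogenic genes (-0.60), osteogenic genes (-0.58) and Hedgehog target genes (-0.52) also lay below all random lists. Adjusted over the list alone, 1 Hedgehog target was lower, and 0 mitotic, histone, chondrogenic or osteogenic genes. The median difference between the 2 SIS3 libraries was larger in size for dental epithelium (1.96), chondrogenic (1.88) and mitotic (-1.16) genes. It was smaller for surface epithelium (1), histone (-0.5), Smad2/3 target (-0.14), matrix (-0.05), osteogenic (-0.03) and Hedgehog (-0.02) genes. Random lists do not show such joint variation. The endothelial (0.04), skeletal muscle (-0.09) and erythroid (0.07) markers lay inside the range of random lists, whereas the pericyte (-0.38, percentile 0.19), macrophage (-0.27, percentile 1.18) and neural (-0.25, percentile 1.55) markers lay below it. Camera with its preset correlation called 14 of the 33 lists, of which 2 hold the same 59 histone genes and were called in all 3 comparisons. The chondrogenic, pericyte, macrophage and neural lists were not among the 14. With an estimated correlation camera called 0 (smallest adjusted p = 0.836), but with 1 residual degree of freedom that setting could hardly call any list. BMP target genes had a median of -0.22 (percentile 0.12) with 0 of 24 called, and the odontogenic mesenchyme genes -0.20 (percentile 0.01) with 0 of 34 called.

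Among the fixed genes, Msx1, a homeobox gene of the dental mesenchyme, had a log2 fold change of -0.61 (95% CI -1.34 to 0.13), Bmp4 -0.31 (-1.11 to 0.50), Smad7 -0.43, Inhba -0.42, Runx2 -0.24, Smad6 -0.23 and Pax9 -0.05. The BMP targets Id1 and Id3 stood at 0.08 and 0.07. The largest differences in the 8-column fit included Aspn (-2.84, SE 0.48), Tmem132b (-4.10, SE 0.77) and C1qtnf3 (-3.88) on the lower side. On the higher side they were Speer4d (3.15), Dnhd1 (2.31), Fsd1 (1.66), Klf15 (1.52), Hpgds (1.48) and Fam124b (1.38). Speer4d shares 74.7% of its 31-mers with other genes, so its count is uncertain. It stood at only 0.226 CPM in DMSO and 2.13 CPM in SB431542. It reached the mean of 5 CPM of the naming rule only through the E13.5 library (19.7 CPM). When each deposited column was taken as a replicate, 95 genes were called higher and 164 lower, which counts the paired columns as separate samples.

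**Figure D1:**
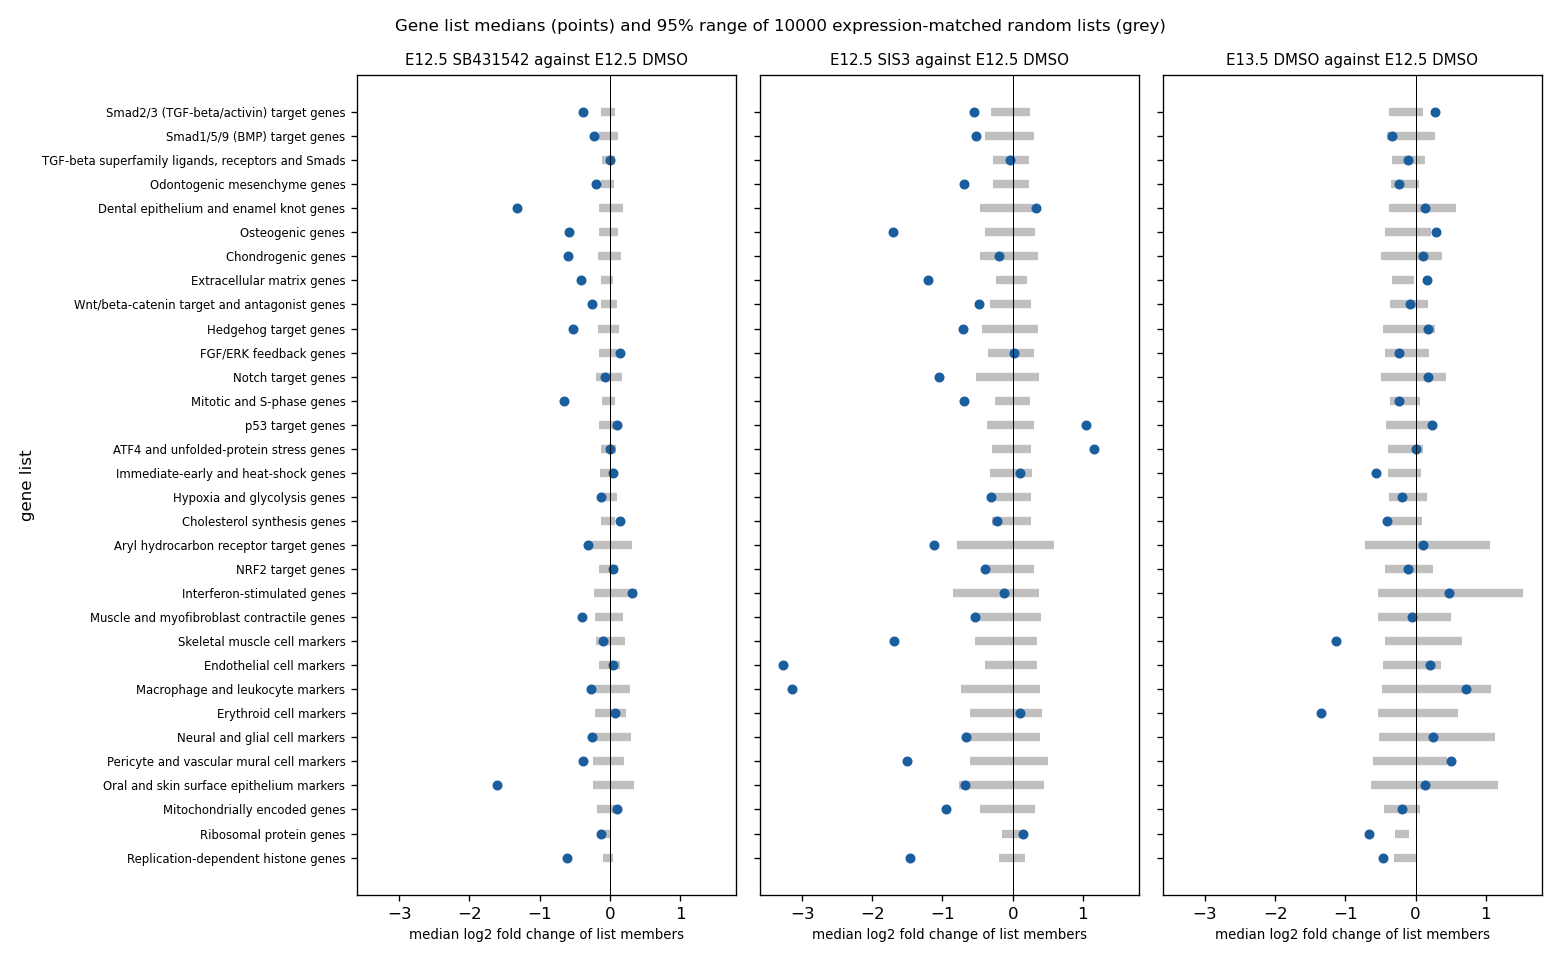
Median log2 fold change of each fixed gene list (points, x axis in log2 units) in 3 comparisons with the E12.5 DMSO library, with the range holding 95% of 10000 expression-matched random lists in grey. Epithelial lists lie lowest with SB431542 (-1.32 and -1.60), and endothelial (-3.27) and macrophage (-3.14) markers lie lowest in the SIS3 libraries, which also differ in library kit.

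The second comparison asked what Smad3 inhibition changed at E12.5, and each of its values holds the kit together with the inhibitor. Endothelial markers were low in both SIS3 libraries: 19 of 23 fell and 0 rose, with a median log2 fold change of -3.27, below all random lists. Kdr (ENSMUSG00000062960; chromosome 5, 75932827 to 75978458, minus strand), which encodes a VEGF receptor, had a log2 fold change of -3.71 (SE 0.31, adjusted p = 1.25e-05 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Cdh5, encoding VE-cadherin, stood at -3.78 (SE 0.31) and Flt1, which encodes another VEGF receptor, at -5.34 (SE 0.45). Macrophage markers had a median of -3.14 with 10 of 22 lower, among them Laptm5 (-4.15), and C1qc at 1 count in both SIS3 libraries together against 197 in DMSO, a ratio of 98.1 (counting interval 17.4 to 3890). Pericyte markers fell in 3 of 9 members (median -1.51), including the channel genes Abcc9 (-2.27) and Kcnj8 (-2.93), and skeletal muscle markers in 5 of 22 (median -1.69), including Ttn (-1.71) and Myh3 (-1.78). Erythroid markers had a median of 0.11 with 1 of 14 called, Hba-a2 (-3.25), which shares 95.1% of its 31-mers with another gene, and neural markers had a median of -0.67 with 0 of 20 called. Kcnj8 and Hba-a2 were not called with trends on GC content and gene length removed, and Kcnj8, Abcc9 and Myh3 not with the libraries of the 2 groups alone. Of 59 replication-dependent histone genes, whose mRNA lacks a poly-A tail, 27 fell and 2 rose (median -1.46). Their median was also low in the SB431542 library (-0.61), which has the same kit as DMSO. Counts of single histone genes can move between near-identical copies. H2ac19 stood at 0 CPM in DMSO and 213 and 212 in the SIS3 libraries, whereas H2ac18 and H2ac19 together stood at 482 and at 330 and 348. Hist1h2bq stood at 0.0323 CPM in DMSO and 69.4 and 45.7 in the SIS3 libraries, and Hist1h2br at 172 and at 0.834 and 0.53. Of 13 mitochondrially encoded genes 4 fell and 2 rose (median -0.95), while their share of counts was 1.31% in DMSO and 1.07% and 1.31% in the SIS3 libraries. The part of the kit in these shifts was not tested. Camera called 17 of the 33 lists with its preset correlation and 0 with an estimated correlation (smallest adjusted p = 0.734).

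Genes of bone formation and matrix were lower as well. Of 18 osteogenic genes 6 fell (median -1.71, 15 lower when adjusted over the list alone). Sp7, encoding the osteoblast factor osterix, had a log2 fold change of -3.34 (SE 0.33, adjusted p = 6.65e-05), and Ibsp (ENSMUSG00000029306; chromosome 5, 104299171 to 104311469, plus strand), encoding bone sialoprotein, had 1 count in the SIS3 libraries together against 2005 in DMSO, a ratio of 998 (counting interval 179 to 39500, adjusted p = 1.33e-07). Of 41 extracellular matrix genes 22 fell and 0 rose (median -1.21, and with the trends removed -1.20 with 10 lower), led by Loxl1 (-4.17, SE 0.33) and Col1a1 (-2.53, SE 0.25). The Smad2/3 target list had a median of -0.55 with 6 of 29 lower: the collagen genes Col1a1, Col3a1 (-1.16) and Col5a1 (-1.14), the crosslinking enzyme gene Lox (-2.10), Ltbp2 (-3.10) and Fst (-1.44). Of these, Col1a1, Col3a1, Col5a1 and Lox are also members of the matrix list. The feedback genes were not called, with Pmepa1 at -0.42 (95% CI -1.14 to 0.30) and Smad7 at -0.58 (-1.21 to 0.05). Odontogenic mesenchyme genes had a median of -0.70 (-0.42 in SIS3 library 1 and -0.90 in library 2) with 4 of 34 lower: Fgf3, at least 23.2-fold lower because it had 0 counts in the SIS3 libraries, Sostdc1 (-1.89), Dlx3 (-3.04) and Dlx2 (-1.33). BMP targets had a median of -0.52 with 2 of 24 lower, Sp7 and Dlx3. The calls of Col3a1, Col5a1, Ltbp2, Fst, Dlx3 and Dlx2 ended with the trends removed, with the libraries of the 2 groups alone and at a mean of 5 CPM or more, and that of Fgf3 ended with the 2 groups alone. Fst and Dlx2 were also not called without the second E12.5 DMSO column.

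Stress genes were higher. Of 29 ATF4 and unfolded-protein stress genes 10 rose and 0 fell (median 1.16, above all random lists), led by Trib3 (ENSMUSG00000032715; chromosome 2, 152337422 to 152344032, minus strand), a pseudokinase gene of the amino acid response (4.35, SE 0.45, adjusted p = 0.000118), with Chac1 (2.66), Asns (2.07) and Sesn2 (2.89). Of 22 p53 target genes 8 rose (median 1.04), with Trp53inp1 (2.76), Ccng1 (1.90) and Zmat3 (1.76) beside Sesn2, which both lists hold. Mitotic and S-phase genes had a median of -0.69 (-0.43 in SIS3 library 1 and -1.23 in library 2) with 5 of 37 lower, the lowest adjusted p values being those of Ccne2 (-2.91), Uhrf1 (-1.64), Rrm2 (-1.67) and Mcm3 (-1.23). These 4 genes were not called at a mean of 5 CPM or more, Rrm2 and Mcm3 not with the 2 groups alone, and Ccng1 and Mcm3 not with the trends removed.

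In all, edgeR called 151 genes higher and 576 lower in the SIS3 libraries, again for inhibitor and kit together, and DESeq2 called 230 and 445. The largest increases by the naming rule were Rps27rt, Hmga1b, Trim66 (5.29), Trib3, Eda2r (4.07) and Slc7a3 (3.99), and the largest decreases were Ibsp, Pet117, Olfr329, Fgf3, Lars2 (-7.35) and Tmem38b (-7.20). Rps27rt, Hmga1b and Pet117 share 82%, 91.5% and 100% of their 31-mers with other genes, and the summed CPM of Rps27 with Rps27rt was 333 in DMSO and 366 and 434 in the SIS3 libraries, while that of Hmga1 with Hmga1b was 64.4 in DMSO and lower, at 40.9 and 59.9, in the SIS3 libraries. Eda2r was not called at a mean of 5 CPM or more, nor Pet117 and Olfr329 with the 2 groups alone. Lars2 took 1.27% to 3.41% of counts in the SMARTer libraries and 0.007% and 0.0095% in the TruSeq libraries. With trends on GC content and gene length removed, 66 genes were called higher and 236 lower, and among genes with a mean of 5 CPM or more 36 and 167.

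The 2 SIS3 libraries differed in some lists. Dental epithelium genes had a median of -0.73 against DMSO in library 1 and 0.90 in library 2, surface epithelium markers -1.62 and -0.12, chondrogenic genes -1.08 and 0.48, and erythroid markers 0.53 and -0.49. The endothelial median was -3.15 and -3.13. Of the fixed genes not named above, these did not pass: Msx1 at -0.62, Bmp4 at -0.74, Smad6 at -0.68, Runx2 at -0.88, Pax9 at -0.39, Inhba at -0.32, Id1 at -0.31 and Id3 at -0.30.

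**Figure D2:**
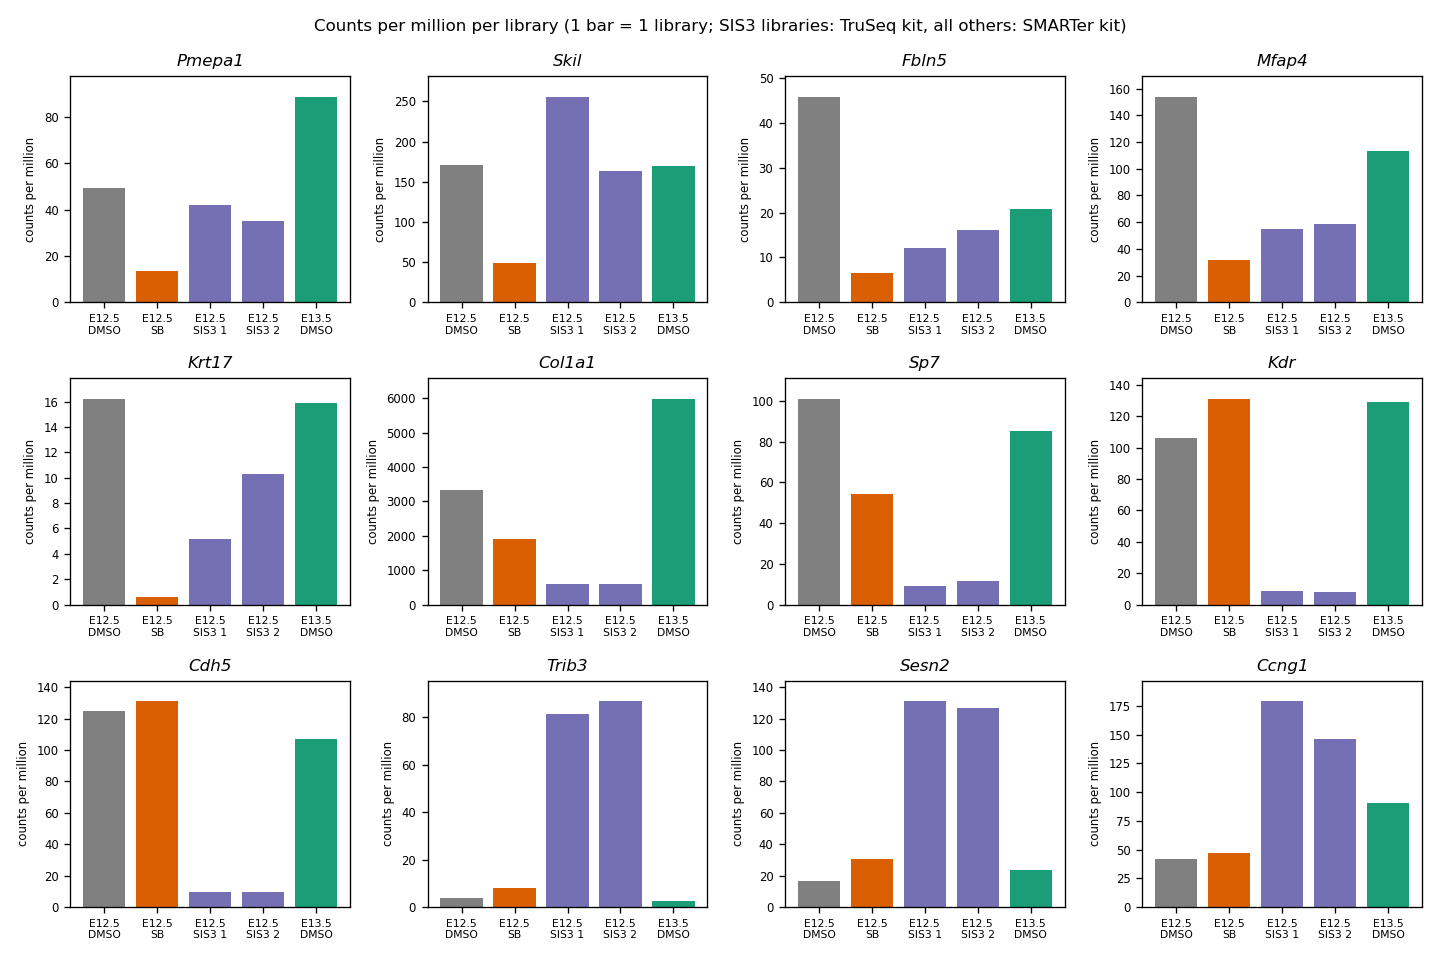
CPM (y axis, linear, from 0) of 12 named genes in each of the 5 libraries, 1 bar per library with no error bar. Pmepa1 and Skil are lowest in the SB431542 library (13.4 and 48.3 CPM), while Kdr and Cdh5 are below 10 CPM in both SIS3 libraries and above 100 CPM in the other libraries.

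The third comparison asked what differed between E13.5 and E12.5 germs in DMSO. Osteogenic genes had a median log2 fold change of 0.29 (percentile 99.1), and edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 2 of 18 higher: Ibsp (2.93, SE 0.38, adjusted p = 0.00107) and Omd, encoding osteomodulin (2.01, SE 0.50, adjusted p = 0.0358). Sostdc1, a secreted BMP and Wnt antagonist, was higher by 1.66 (SE 0.37, adjusted p = 0.0228), and of 17 surface epithelium markers 2 rose, the oral keratins Krt13 (6.39, SE 0.63) and Krt4 (4.17, SE 0.73), and 1 fell, Dsc3 (-2.46). Skeletal muscle markers had a median of -1.14 with 3 of 22 lower, all at 0 counts in the E13.5 library: Myod1 at least 45.1-fold, Pax7 at least 20.9-fold and Tnnc2, which shares 60.2% of its 31-mers with another gene, at least 22.8-fold lower. Of the erythroid markers, the embryonic globin Hbb-bh1 fell by 3.58 (SE 0.82, adjusted p = 0.026), with a list median of -1.35, or -1.04 with the member at 0 set to its bound. Smad2/3 targets had a median of 0.28 (percentile 99.93) with 1 of 29 called, Tagln at 1.77 (adjusted p = 0.0482), and Pmepa1 stood at 0.89 (95% CI 0.04 to 1.73, not called). Omd, Sostdc1, Dsc3, Pax7, Tnnc2, Hbb-bh1 and Tagln were not called in a refit without predicted genes and pseudogenes, and all of these except Sostdc1 were also not called without either E13.5 column.

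Matrix genes had a median of 0.16, above 99.99% of random lists, with 0 of 41 called. Immediate-early and heat-shock genes had a median of -0.57 with 2 of 27 lower, Fos (-1.75) and Hspb1 (3 counts at E13.5 against 133, a ratio of 25.1, counting interval 8.4 to 123). Ribosomal protein genes had a median of -0.67 with 12 of 85 lower, including Rps21 (-2.34) and Rps28 (-2.31). Fos and Hspb1 were not called without receptor genes, predicted genes, pseudogenes and near-identical copies. Camera called 6 of the 33 lists with its preset correlation and 0 with an estimated correlation (smallest adjusted p = 0.994), where 1 residual degree of freedom could hardly give a call. The 6 included the ribosomal protein, histone, immediate-early, skeletal muscle and cholesterol synthesis lists, the last with a median of -0.41 (percentile 1.78). The Smad2/3 target, osteogenic, erythroid and matrix lists were not among them. Of the fixed genes, Id1 stood at -1.31 (95% CI -2.27 to -0.35), Smad7 at -0.57, Msx1 at -0.35, Bmp4 at 0.17 and Inhba at 0.54, none of them called.

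For the stage as a whole, 772 genes were called higher and 223 lower, and these counts rest on few certain genes. Of the 772 higher, 161 were olfactory or vomeronasal receptor genes and 340 other predicted genes or pseudogenes. Olfactory receptor genes took 1.16% of counts in the E13.5 library against 0.332% in E12.5 DMSO. A refit without receptor genes, predicted genes, pseudogenes and near-identical copies called 30 higher and 9 lower, although 391 of the 995 called genes were in that refit. Leaving out either E13.5 column gave 334 and 327 higher, and leaving out the second E12.5 DMSO column gave 502. Without near-identical copies alone, 1066 were called higher and 426 lower. The largest differences by the naming rule include such genes, with H2ac19 (100% shared 31-mers, at least 2630-fold higher), Fam177a (99.2%, at least 102-fold lower) and Olfr1565 (100%, at least 78.8-fold lower). H2ac18 and H2ac19 together stood at 345 CPM against 482, and the 4 genes of the H2ac19 family, grouped by shared 31-mers, at 571 against 585. Among those sharing 1.1% or less were Fsip2, with 1043 counts against 1 (ratio 1840, counting interval 330 to 72900), Pkd1l3 (6.90, SE 0.99), Arsg (at least 16.4-fold lower) and Stc2 (at least 11.5-fold lower). Arsg and Stc2 were not called in the refit without the doubtful classes, nor Stc2 at a mean of 5 CPM or more.

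The inhibitors were also set beside each other directly, again with the kit. Between SIS3 and SB431542 465 genes were called. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, Pmepa1 was higher in SIS3 than in SB431542 by 1.51 (SE 0.37, adjusted p = 0.0479), Trim66 by 6.25 and Slc7a3 by 3.96, and Ibsp was lower by a ratio of 413 (counting interval 74 to 16400). Skil was higher in SIS3 by 2.10 (SE 0.38, adjusted p = 0.0115). Neither Pmepa1 nor Skil was called with GC and length trends removed, with the 2 groups alone or at a mean of 5 CPM or more, and Pmepa1 was also not called without either SB431542 column. Between the SB431542 and E13.5 DMSO libraries 736 genes were called, and 6 of 29 Smad2/3 target genes (median -0.69) and 9 of 41 matrix genes (median -0.59) were lower in SB431542. Across the 19022 genes, the log2 fold changes of SB431542 and SIS3 correlated with r = 0.31 (Spearman's rho 0.348). Unchanged libraries simulated against the shared DMSO library gave a mean r of 0.54, and the covariance was 0.197 against a simulated 0.238. With E13.5 DMSO as the reference of SIS3, which removes the shared library but brings in the stage difference, r was -0.049 and the covariance -0.055. That covariance is the SIS3 covariance minus the stage covariance given next, so it is no separate test of a shared response. Fold changes of SB431542 and of the stage correlated with r = 0.251 (rho 0.22) against a simulated 0.488, with a covariance of 0.252 against 0.238. With each deposited column as a replicate, 136 of the 164 genes lower in SB431542 were also lower in SIS3 (33.3 for independent lists) and 50 of 95 were higher in both (16.9), while 7 and 27 went opposite ways (29.2 and 19.3). With the stage, 50 were lower in both (41.4) and 65 higher in both (28.1), and 40 and 13 went opposite ways (48.6 and 24). Part of any excess may come from the shared control. Genes are not independent replicates, so these values describe the libraries, and neither r exceeds the simulated r. The simulated values rest on the spread of the SIS3 pair, and real changes that the arms do not share also lower r. A shared response is therefore neither shown nor excluded.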

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

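The fits without classes of genes were chosen after the results had been seen, and the other alternatives before the data were examined. The fit of the SIS3 comparisons without non-polyadenylated, mitochondrial, ribosomal protein and predicted genes was also planned. The fit on all deposited columns was the planned one, and summing paired columns was chosen after the columns had been compared. Counts are given as higher and lower, or as 1 number for SIS3 against SB431542 and for SB431542 against E13.5 DMSO, and where no reason is given the cause was not tested.

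For SB431542 against DMSO, 0 and 0 genes became 0 and 4 with DESeq2, 8 and 19 with no filter on low counts, and 0 and 6 without near-identical copies. For SIS3, 151 and 576 became 335 and 1079 with no filter, 36 and 167 at a mean of 5 CPM or more, 63 and 169 with the libraries of the 2 groups alone, 80 and 320 against a fold of 1.5, 66 and 236 with GC and length trends removed, 61 and 290 when called against each of the 3 SMARTer libraries, 61 and 259 without predicted genes, pseudogenes, receptor genes and near-identical copies, and 69 and 291 without predicted genes and pseudogenes. DESeq2 called 230 higher. For the stage, 772 and 223 became 439 and 135 with DESeq2, 1458 and 604 with no filter, 174 and 35 at 5 CPM or more, 30 and 9 without all doubtful classes, 378 and 122 without receptor genes, and 105 and 27 without predicted genes and pseudogenes. A fold of 1.5 left 143 lower, and without copies 426 were lower.

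For SIS3 against SB431542, 465 became 1027 with no filter, 89 at 5 CPM or more, 166 with the 2 groups alone, 272 against a fold of 1.5, 152 with trends removed, 197 without all doubtful classes and 229 without predicted genes and pseudogenes. For SB431542 against E13.5 DMSO, 736 became 1884 with no filter, 63 at 5 CPM or more, 429 against a fold of 1.5, 19 without all doubtful classes, 1277 without copies, 378 without receptor genes and 64 without predicted genes and pseudogenes. The degrees of freedom borrowed across genes were 5.5 at 5 CPM or more, 6.4 with trends removed, unlimited with no filter, 9.3 without all doubtful classes and 29 without copies, and their part in the counts was not tested.

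With each deposited column as a replicate, the calls were 95 and 164 (SB431542), 3157 and 3607 (SIS3), 5257 and 4485 (stage), 5805 and 9850. On the SMARTer columns alone they were 1606 and 1995 (SB431542), 6604 and 6111 (stage) and 12832. With the replicate number as a block in the paired fit they were 19 and 64, 2848 and 3346, 5006 and 4254, 5191 and 9347, and with the block and trends removed 2742 and 3367 for SIS3 and 5230. Differences between same-numbered columns correlated by -0.017 to 0.021, so the numbers do not pair the columns.

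Leaving out each deposited column in turn gave 0 to 0 higher and 0 to 1 lower for SB431542, 141 to 150 and 500 to 558 for SIS3, 327 to 649 and 72 to 198 for the stage, 412 to 438 for SIS3 against SB431542 and 249 to 520 for SB431542 against E13.5 DMSO. Leaving out an E13.5 column lowers the depth of that library. Without a SIS3 library, and for SB431542, the stage and SB431542 against E13.5 DMSO with the 2 groups alone or the SMARTer libraries alone, no residual degree of freedom remained among the summed libraries and no test was made.

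Camera's 14, 17 and 6 called lists for SB431542, SIS3 and the stage became 0, 0 and 0 with an estimated correlation and 1, 1 and 0 with fry. The loss with an estimated correlation decides nothing, since with 1 residual degree of freedom that setting could hardly call any list. The correlation of SB431542 with SIS3 was 0.31, and 0.201 and 0.187 with a different E12.5 DMSO column per comparison. With E13.5 DMSO as the reference of SIS3 it was -0.049, but that value also holds the stage difference and is no separate test. That of SB431542 with the stage was 0.251, and 0.191 at 5 CPM or more, and 0.175 and 0.17 with a different column per comparison. Over the largest changes and the fixed genes, in the 3 comparisons with E12.5 DMSO and outside the fold of 1.5 and the fits without classes of genes, 512 values stayed on their side of the threshold (69 of them, from leaving out a column or SIS3 library, checked for direction only), 78 passed it and 5 lost it: Eda2r and Stc2 at 5 CPM or more, and Pet117, Olfr329 and Fgf3 with the 2 groups alone. Of all 155 genes called for SIS3 that the naming rule or a list holds, 140 were called with DESeq2, 66 at 5 CPM or more, 69 with the 2 groups alone, 100 against a fold of 1.5, 81 with trends removed and 90 without all doubtful classes. Without non-polyadenylated, mitochondrial, ribosomal protein and predicted genes 113 were called, 2 were not and 40 were not in that fit. For the 74 calls that ended with trends removed, the median size of the log2 fold change went from 1.75 to 1.53 and the median SE from 0.35 to 0.39. Of 50 such genes for the stage, 38 were called with DESeq2, 19 at 5 CPM or more, 34 against a fold of 1.5, 23 without predicted genes and pseudogenes, 10 without all doubtful classes (14 were not in that fit), and 28 to 45 without a column. Of 51 for SB431542 against E13.5 DMSO, 6 were called at 5 CPM or more, and of 99 for SIS3 against SB431542, 29. None changed direction in any alternative.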

Other observations

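The tests of all cell types falling alike and of the library kit were chosen after their results had been seen, as were the intervals required of every test below and how they are read, and the test of a smaller epithelial share replaced an earlier one that could not decide. These 95% intervals are taken over genes as if genes were independent. They hold no spread between libraries or cultures, so what they argue for or against covers these libraries only.

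Other gene groups also differed between the libraries. In the SIS3 libraries, which also differ in kit, 4 of 41 TGF-beta superfamily genes fell and 1 rose: the ligand genes Gdf10 (log2 fold change -2.48) and Tgfb1 (-2.48) and the receptor genes Eng (-2.15) and Tgfbr2 (-1.33) were lower, and Bmpr1b (2.19) was higher. Of 30 Wnt target and antagonist genes 3 fell and 1 rose, with Tcf7 at -3.15, Sfrp1 at -1.22 and Rspo2 at 1.48. Notch targets had a median of -1.05, or -0.53 with the member at 0 counts set to its bound, and 1 of 16 was lower, Heyl (-3.28). Immediate-early genes had 3 of 27 higher, Nr4a1 (2.13), Atf3 (2.33) and Btg2 (1.63). Eng, Tgfbr2, Bmpr1b, Sfrp1, Rspo2, Heyl and Atf3 were not called with trends on GC content and gene length removed, and these with Nr4a1 and Btg2 not with the libraries of the 2 groups alone or at a mean of 5 CPM or more. At E13.5 the interferon-stimulated genes Rsad2 (5.42) and Irf7 (4.56) were higher, 2 of 22 in that list, while Gadd45a (-2.58) and Chac1 (-2.36) were lower, and none of these 4 was called without predicted genes and pseudogenes. In the SB431542 library Cyp1b1, a dioxin-responsive oxidase gene, stood at 10.9 CPM against 65.6 in DMSO (-2.65, SE 0.53) and the lipid desaturase gene Scd1 at 224 against 105 CPM (1.03, SE 0.37), neither of them called.

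In the SIS3 libraries endothelial and macrophage markers were lower and ATF4 and p53 target genes higher. With trends on GC content and gene length removed, the endothelial median was -3.22 (interval -3.57 to -2.28) and 14 of 23 markers were still called. The ATF4 median was 1.24 (0.446 to 1.8) with 7 of 29 still called. In these libraries both medians lay beyond what these trends as the whole cause would leave. Called macrophage markers went from 10 to 4 of 22 (median -3.24) and p53 targets from 8 to 5 (median 1.16). A loss of every non-mesenchymal cell type alike is argued against by the dental epithelium median lying 2.42 above the endothelial one in the SIS3 library where the gap was smaller (interval 1.33 to 3.02). Of the endothelial markers 91.3% (interval 72 to 98.9) were lower in both SIS3 libraries than in every SMARTer library, which the kit and the inhibitor would give alike, so the 2 cannot be told apart. A lower share of vessels and macrophages in the dissected or cultured germs was not tested.

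Among the genes called between E13.5 and E12.5 DMSO, 77.6% were higher. Outside receptor genes, predicted genes, pseudogenes and near-identical copies 63.9% (interval 59 to 68.7) were higher, a smaller excess, but refits called 30 higher and 9 lower without all these classes, 105 and 27 without predicted genes and pseudogenes, and 378 and 122 without receptor genes. These values point different ways, so whether such genes are the source stays open. Near-identical copies made up 28% (24.8 to 31.4) of the genes called higher, 208 of 743, and 60 of 215 of those called lower. Called genes held copies more often than tested genes did, since 17139 of the 19022 tested genes were not such copies. The 28% lay between the bounds set beforehand for and against this cause, so by those bounds it did not decide. A like share in both directions argues against reads moved between copies as the whole source of the excess, though not as a part of it. The difference in stage itself stays open, as untested.

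In the SB431542 library epithelial markers lay lowest. A smaller share of epithelial cells may be the source, and it would lower other epithelial genes too. The 34 genes outside every list that were at least 4-fold higher in SIS3 library 2 than in library 1, between which dental epithelium genes differed by a median of 1.96, had a median of -0.28 (interval -0.485 to -0.0929) in SB431542. The 70 genes with the opposite difference had a median of -0.30. The 2 SIS3 libraries also differed in chondrogenic genes (median 1.88) and mitotic genes (-1.16), so the 34 genes need not be epithelial. The test therefore did not separate a smaller share from a change within the epithelium.

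Counts of some copies moved between libraries as if exchanged. There were 4 genes at 0 counts in E12.5 DMSO and SB431542 and above 5 CPM in the other 3 libraries, and 7 genes with the opposite pattern, and 10 of these 11 shared 50% or more of their 31-mers with another gene. H2ac18 and H2ac19 together stood at 482, 398, 330, 348 and 345 CPM in E12.5 DMSO, SB431542, SIS3 library 1, SIS3 library 2 and E13.5 DMSO, although H2ac19 alone was at 0 in the first pair and at 212 to 254 in the others. In the same order, the 4 genes of the H2ac19 family together stood at 585, 478, 438, 435 and 571 CPM. Gm10800 took 0.988% of the counts of the E13.5 library and 0.0041% of those of E12.5 DMSO.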
